A study of Mus musculus with 13 samples.

How the data were processed

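RNA sequencing libraries of macrophages from mouse optic nerve (4) and sciatic nerve (4) and of microglia from mouse brain (5), 13 in all, were analysed from the count table of the series. The samples were total RNA of C57BL/6J mice, per the labels. The microarray and single-cell parts of the series were not analysed here. The deposited values are raw read counts per gene symbol, made by the authors with STAR alignment to mm10 and featureCounts 1.5.1, per the submitters' processing notes. The version of STAR, the gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The table holds 48587 gene symbols, and all values are whole numbers. The number of columns with per-sample values that were not used is 0. Columns of the nerves carry the initials and replicate numbers of the tissues, and the 5 columns with an unexplained prefix were taken as brain microglia by elimination, as the group with 5 replicates.

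Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, which left 13246, and libraries were scaled by TMM. All 13 libraries entered 1 quasi-likelihood fit with tissue as the factor and no replicate block, so that the tissues share 1 estimate of the spread, and the 3 pairwise contrasts were tested with edgeR's quasi-likelihood F-test and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05, and calls with a log2 fold change of at least 1 in size were counted apart. A gene counts for a tissue against both others when both of its contrasts are called in the same direction. Levels are CPM (counts per 1e6 of the TMM-scaled library size), and log2 CPM for distances, principal components and list tests used a prior count of 2. Standard errors of log2 fold changes come from the fit.

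Total counts per library ran from 10.9 to 23.5 M. A count of 0 over a whole group allows a level of up to 0.0512 CPM in sciatic nerve, 0.0409 CPM in optic nerve and 0.0265 CPM in brain (3 counts over the group). Against a group with 0 counts a fold is given as at least the ratio to that floor, and against a group with 1 to 3 counts as a ratio with its 95% Poisson counting interval. These intervals and floors cover counting error only, since duplicate reads are not independent molecules.

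The test was run on simulated counts with the means and library sizes of the real libraries, with 200 genes changed, 100 by each fold size, in 5 simulations per comparison. It recovered 27.6% of genes changed by 1 in log2 and 71.4% of those changed by 2 for sciatic nerve against brain, 24.0% and 64.8% for optic nerve against brain, and 19.4% and 60.8% for sciatic against optic nerve. Many more genes were called in the real libraries than were changed here. The adjustment was therefore stricter in the simulations, and these shares may understate the recovery in the real libraries. The mean share of false calls was 4.39%, 4.86% and 5.63% in the same order, with up to 12.2% in 1 simulation of the last. Of 100 simulated unchanged lists 2, 1 and 0 were called, and of 100 raised lists 100 in each comparison. The simulated genes were drawn independently of each other. These shares therefore do not give the rate of false calls for the real lists, whose members can move together (estimated correlation 0.192 for microglia identity). On 5000 simulated genes the position along the brain to sciatic nerve axis was recovered as 0.253, 0.506 and 0.749 for simulated values of 0.25, 0.5 and 0.75. The nearness test gave exact permutation p = 0.00794, 0.0476 and 0.00794 there, so it called a nearer tissue at 0.5, where there was none (-0.0131). In 200 further simulations at 0.5 it did so in 41 (20.5%), with p under 0.02 in 20, so its p-values are too small.

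The 33 gene lists, the rule for named genes, the tests of genes and lists and all alternatives but 1 were fixed before the data were examined, the lists from textbook knowledge. Some tests of technical explanations were chosen after the results were seen. The lists cover microglia identity, border and perivascular macrophages, alternatively activated macrophages, MHC class II presentation, type I interferon response, disease-associated microglia, efferocytosis and scavenger receptors, complement, TGF-beta signalling, chemokines, inflammatory cytokines, immediate early and dissociation response, cell cycle, lysosome, cholesterol and lipid handling, iron and haem handling, macrophage transcription factors, growth factors and purinergic signalling. They also cover markers of monocytes, neutrophils, dendritic cells, lymphoid cells, mast cells, Schwann cells, oligodendrocytes, astrocytes, neurons, fibroblasts, endothelial cells, adipocytes and muscle, mitochondrially encoded genes and sex-linked genes. Some genes are on several lists, such as Cd163, Cd36, Mrc1 and Sall1. Each list with at least 3 tested members was tested per contrast with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists tested. Camera with an estimated correlation and fry were alternatives. Members were also counted with p-values adjusted over the list alone.

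Genes are named by 4 parts of a rule. Part (a) takes, per contrast, the 8 called genes with the largest positive and the 8 with the largest negative log2 fold change among those with a mean of at least 32 CPM in the higher group and no overlap between the libraries of both groups, leaving out unnamed loci, mitochondrially encoded genes and immunoglobulin or T cell receptor segments. Part (b) takes, per list and contrast, up to 2 called members at each end, or the member with the highest mean where none is called. Part (c) takes 5 genes for each of the 6 patterns in which 1 tissue differs from both others. Part (d) always includes P2ry12, Tmem119, Sall1, Cx3cr1, Csf1r, Adgre1, Fcgr1, Ptprc, Mrc1, Retnla, H2-Aa, Ccr2, Apoe, Trem2 and 1 gene that is not reported here.

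Shared calls between contrasts that share libraries were set beside the number for independent lists, the number in 10 simulations without a difference and the number with the shared libraries split in 2. Nearness of the optic nerve is the mean Euclidean distance of log2 CPM per gene to sciatic nerve libraries minus that to brain libraries, with an exact two-sided permutation test. For the position of the optic nerve, the axis was taken from some of the brain and sciatic nerve libraries and its ends from the others. Gene coordinates come from GENCODE M21 on GRCm38, matched by symbol. Of the 48587 symbols 46471 (95.6%) had a transcript there, and of the 181 named genes 179 were placed, all but Fam212a and Tmem8c. Alternatives were DESeq2 size factors, upper-quartile scaling, no filter, a filter at 10 CPM in at least 4 libraries, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, fits of only the groups compared, other prior counts and gene selections for the distances, and leaving out each library in turn. Leaving out brain replicates 1 and 2 together was chosen after seeing the data. Figures and tables of flags were made with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.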

Results

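RNA was sequenced from macrophages of the mouse optic nerve (4 libraries) and sciatic nerve (4 libraries) and from brain microglia (5 libraries), all from the C57BL/6J strain. The series asks what sets macrophages of the peripheral nervous system apart from those of the central nervous system, and 3 pairwise comparisons of the tissues follow from its design. The optic nerve belongs to the central nervous system and the sciatic nerve to the peripheral. Total counts per library were 17.2 ± 1.23 M in sciatic nerve (mean ± SD, n = 4), 18.9 ± 1.73 M in optic nerve (n = 4) and 19.6 ± 5.17 M in brain (n = 5), with a range from 10.9 to 23.5 M. Levels are in CPM, counts scaled to a common library size after TMM normalisation, as mean ± SD over 4 sciatic nerve, 4 optic nerve or 5 brain libraries. The labels do not name separate animals, so the replicates may be technical, and the p-values then measure the spread between samples only. The brain columns of the count table were assigned by elimination, and P2ry12, Tmem119 and Sall1, all known from microglia, were highest in those columns.

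The libraries of each tissue lay together. The first 3 principal components held 55.4%, 14.6% and 6.76% of the variance of log2 CPM. Across genes, which are not independent replicates, the mean Pearson correlation of log2 CPM was 0.662 between sciatic nerve and brain libraries, 0.810 between optic nerve and brain, 0.825 between sciatic and optic nerve, and 0.925 to 0.936 between libraries of 1 tissue. Brain replicate 1 stood apart. It had 10.9 M counts, 3.79% of them on mitochondrially encoded genes against 0.410% to 0.868% in the other brain libraries, and its mean correlation with them was 0.892 against 0.923 to 0.937 for the others. Replicate 2 also differed from replicates 3 to 5, which correlated with each other at 0.966 to 0.971. It correlated with them at 0.927 to 0.928 and with replicate 1 at 0.911, and on component 3 replicates 1 and 2 stood at -103.76 and -27.92, against 46.25 to 52.38 for the others. P2ry12 measured 4841 and 5897 CPM in replicates 1 and 2 and 10294 to 10466 CPM in the others, and Maf, a transcription factor, 837 and 529 CPM against 231 to 262 CPM.

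**Figure D1:**
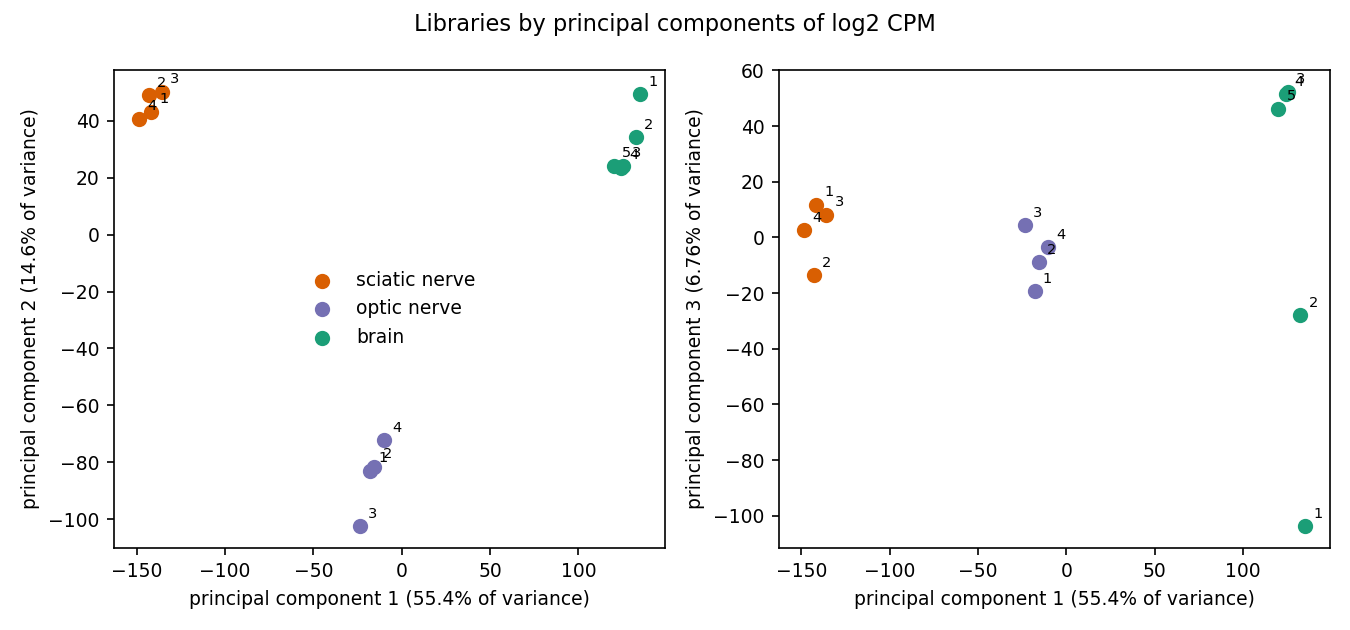
Each point is a library of sciatic nerve, optic nerve or brain, placed by its score on principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM, in log2 units. Component 1 (55.4% of the variance) orders the tissues from brain through optic nerve to sciatic nerve.

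In sciatic nerve macrophages genes known to mark microglia were far lower than in brain microglia. Sall1, a transcription factor that maintains microglial identity, measured 0.137 ± 0.0802 CPM in sciatic nerve and 408 ± 13.8 CPM in brain (log2 fold change -11.48, SE 0.47). Tmem119, a microglial surface protein, measured 6.85 ± 1.85 against 4732 ± 918 CPM (log2 fold change -9.43, SE 0.31), and P2ry12, a purinergic receptor of resting microglia, 141 ± 12.6 against 8377 ± 2772 CPM (log2 fold change -5.89, SE 0.27). Higher in sciatic nerve were Retnla, a secreted protein of alternatively activated macrophages, at 14433 ± 4615 CPM with 0 counts in brain (at least 544317-fold higher), and Cd163, the scavenger receptor for haemoglobin and haptoglobin, at 1323 ± 221 CPM (149739-fold, 95% counting interval 26875 to 5914356, higher). The antigen-presenting gene H2-Aa reached 13079 ± 1355 CPM against 1.87 ± 2.54 CPM (log2 fold change 12.73, SE 0.99). The adjusted p of these 6 genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 7.83e-12 to 6.47e-08, and the libraries of both tissues did not overlap for any of them.

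All 18 tested genes of the microglia identity list fell in sciatic nerve relative to brain (18 of 18 when adjusted over the list alone, camera adjusted p = 9.28e-16, adjusted p = 0.0121 with an estimated correlation). Among them, Slc2a5, a fructose transporter, measured 0.700 ± 0.391 against 1156 ± 269 CPM, and Sall3 also fell (log2 fold change -10.04, SE 0.51). The mean log2 CPM of the list was 4.88 ± 0.12 in sciatic nerve and 10.58 ± 0.25 in brain, where replicate 1 had the lowest value (10.16 against 10.52 to 10.74). All 16 tested genes of the border and perivascular macrophage list rose, also adjusted over the list alone (camera adjusted p = 1.27e-14, adjusted p = 0.0121 with an estimated correlation). Among them were Mrc1, the mannose receptor (1987 ± 331 against 15.3 ± 6.87 CPM), and Clec4n, a lectin receptor (at least 5802-fold higher). Of the alternatively activated macrophage list, 8 of 10 rose and none fell, 8 when adjusted over the list alone (camera adjusted p = 1.06e-06), and the lectin receptor Mgl2 reached 3697 ± 286 CPM (log2 fold change 16.43, SE 0.56). Markers of another cell type moved with these groups, since all 8 tested fibroblast genes rose as well (8 adjusted over the list alone, camera adjusted p = 8.20e-05, and adjusted p = 0.0576 with an estimated correlation). Of these, Dcn, a matrix proteoglycan, was uneven between libraries at 32.7 ± 34.2 CPM, and Gsn, an actin-binding protein, was more even at 210.2 ± 47.0 CPM.

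Antigen presentation genes went both ways. Of 12 tested members of the MHC class II list, 7 rose and 3 fell in sciatic nerve, the same numbers when adjusted over the list alone (camera adjusted p = 0.00960, adjusted p = 0.148 with an estimated correlation). H2-Eb1 rose to 8590.2 ± 1337 CPM, while H2-Oa, which restrains peptide loading, fell to 1.61 ± 1.31 against 49.8 ± 8.41 CPM, and Ctss, a cathepsin, fell with a log2 fold change of -1.53 (SE 0.16). Of the 16 type I interferon response genes 15 rose and none fell, 15 when adjusted over the list alone (camera adjusted p = 9.45e-08, adjusted p = 0.0916 with an estimated correlation), led by Ifitm3, an inhibitor of viral entry, at 1229 ± 149 against 12.5 ± 4.36 CPM. The disease-associated microglia list split, with 10 genes higher, 5 lower and 1 not called (10 and 5 adjusted over the list alone), and was not called as a list (camera adjusted p = 0.0863). Apoe, the lipid carrier, rose to 25973 ± 5802 CPM from 307 ± 101 CPM, while Trem2, a lipid-sensing receptor, fell to 187 ± 39.1 from 1726 ± 392 CPM.

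Chemokine and early response transcripts were abundant in sciatic nerve and scarce in brain. Cxcl2 and Cxcl1, which attract neutrophils, measured 5902 ± 1870.2 and 3349 ± 934 CPM with 0 counts in brain (at least 222571-fold and at least 126315-fold higher). Of 17 tested chemokines 15 rose (15 adjusted over the list alone, camera adjusted p = 1.42e-12, adjusted p = 0.0171 with an estimated correlation). Of 12 genes of the inflammatory cytokine list 10 rose (10 adjusted over the list alone, camera adjusted p = 1.58e-08, adjusted p = 0.0160 with an estimated correlation), among them Il10 at 222 ± 65.4 CPM (at least 8372-fold higher). Despite its name, this list also holds Il10, an anti-inflammatory cytokine, and Nlrp3, Ptgs2, Nfkbiz and Nfkbia, which are not cytokine genes. The immediate early and dissociation response list had 19 of 20 genes higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 1.27e-14, adjusted p = 0.0146 with an estimated correlation). Fos rose (log2 fold change 11.34, SE 0.51) and Rhob, a small GTPase, fell (log2 fold change -1.85, SE 0.23). Brain replicate 1 had the lowest mean log2 CPM of this list among the brain libraries (2.92 against 3.55 to 3.83).

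Iron handling genes rose, 12 of 14, with 1 lower, the same adjusted over the list alone (camera adjusted p = 1.20e-05). Hmox1, the haem-degrading oxygenase, rose to 1162 ± 422 CPM, and Slc40a1, the iron exporter ferroportin, fell to 139 ± 22.6 from 409 ± 125.8 CPM. Of 26 macrophage transcription factors 15 rose and 8 fell (15 and 9 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0697, and 0.0468 without optic nerve replicate 1). Pparg, a lipid-sensing nuclear receptor, was at least 1469-fold higher and Id3, an inhibitor of helix-loop-helix factors, 11966-fold, 95% counting interval 2148 to 472649, higher. Of 12 complement genes 7 rose and 4 fell, the same adjusted over the list alone, without a call for the list (camera adjusted p = 0.0863). Properdin (Cfp) rose to 1149 ± 144 from 1.49 ± 1.59 CPM and Itgam, an integrin and complement receptor, fell to 235 ± 38.2 from 1002 ± 453 CPM.

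Among the other named genes of this comparison, Tnip3, an inhibitor of inflammatory signalling, reached 729.6 ± 109.8 CPM (at least 27515-fold higher), and Pla2g2d, a secreted phospholipase, 412 ± 53.2 CPM (at least 15555-fold higher). On the brain side, B3galt5, a galactosyltransferase, had 0 counts in sciatic nerve and 35.3 ± 11.9 CPM in brain (at least 690.0-fold lower), and Slco4a1, an organic anion transporter, was 3482-fold, 95% counting interval 625 to 137515, lower. Upk1b measured 155 ± 18.8 CPM in brain, Lrrc3 268 ± 59.4 CPM and Tmem204 95.6 ± 22.7 CPM, and each fell in sciatic nerve (-10.72, -10.31 and -10.31 in log2). In all, 3191 of 13246 tested genes were higher and 3219 lower in sciatic nerve than in brain, of which 2387 and 2551 by at least 2-fold. The libraries of both tissues did not overlap for 5471 genes (41.3%), against 1.59% by chance.

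**Figure D2:**
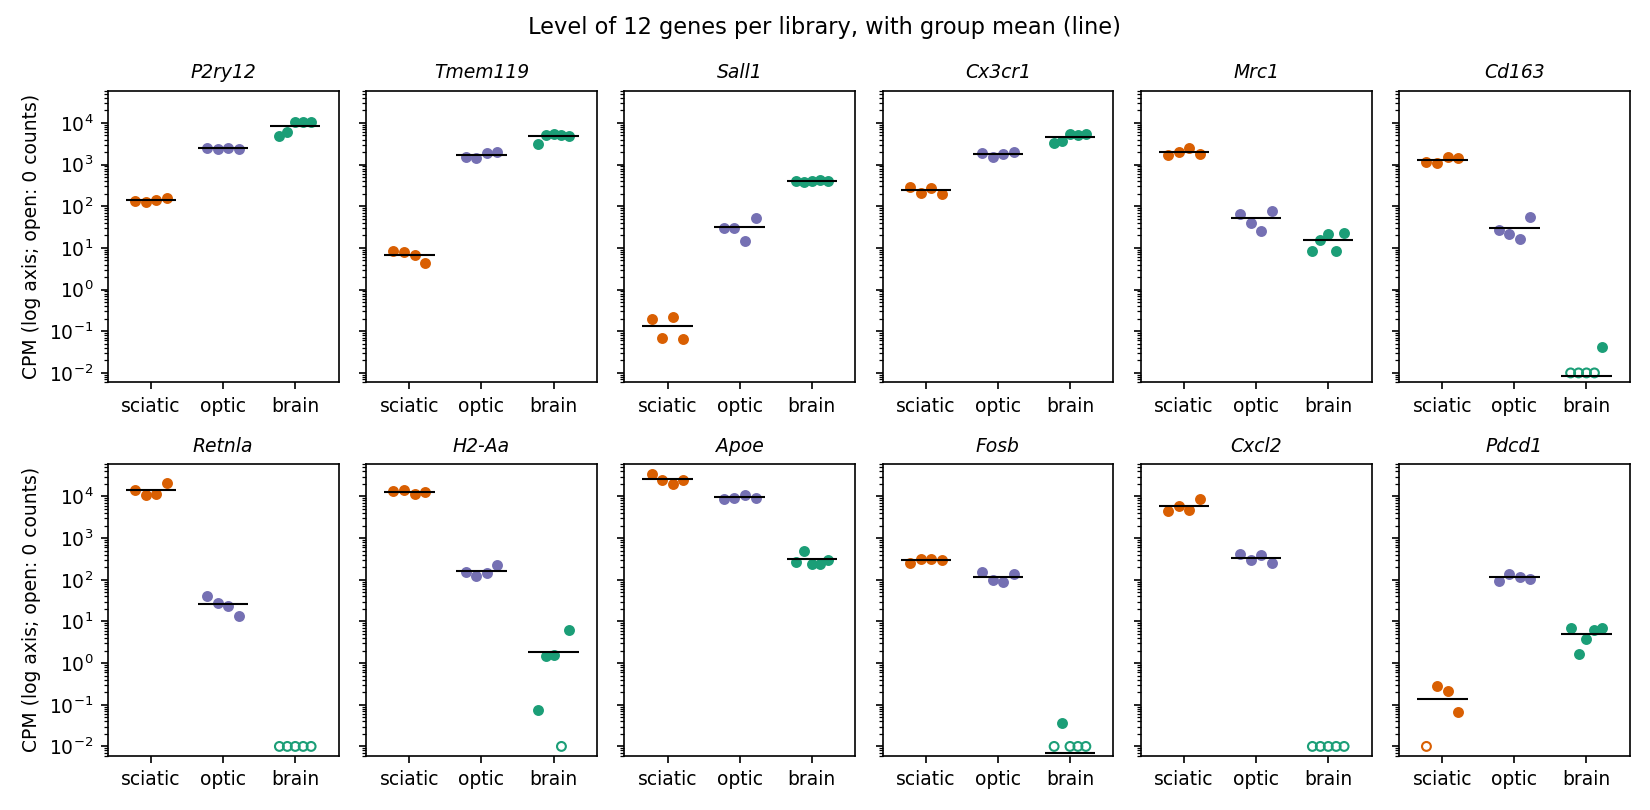
CPM of 12 genes in each library on a log axis, by tissue, with the group mean as a line and open symbols for libraries with 0 counts. Sall1 and P2ry12 fall from brain through optic nerve to sciatic nerve, Retnla, Mrc1 and H2-Aa run the other way, and Pdcd1 is highest in optic nerve at 114 ± 19.95 CPM.

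Optic nerve macrophages expressed most microglial genes, at lower levels than brain microglia. P2ry12 measured 2457 ± 103 CPM in optic nerve (log2 fold change -1.77, SE 0.22 relative to brain), Tmem119 1731 ± 314 CPM (log2 fold change -1.45, SE 0.21) and Cx3cr1, the fractalkine receptor, 1808 ± 199.6 against 4641 ± 1016 CPM (log2 fold change -1.36, SE 0.19). Sall1 fell further, to 32.3 ± 15.9 CPM (log2 fold change -3.66, SE 0.30). Trem2 was not called, at 1563 ± 212 against 1726 ± 392 CPM. Higher in optic nerve were Cxcl2 (336 ± 74.8 CPM and 0 counts in brain, at least 12687-fold higher), Fosb, an immediate early transcription factor (119 ± 30.3 CPM, 13468-fold, 95% counting interval 2417 to 531963, higher), and Apoe (9503 ± 1076 CPM, log2 fold change 4.95, SE 0.24). The adjusted p of these 7 called genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 5.24e-12 to 9.78e-05.

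Of 18 tested microglia identity genes 14 fell in optic nerve relative to brain and none rose, 15 when adjusted over the list alone (camera adjusted p = 1.98e-06, adjusted p = 0.0563 with an estimated correlation). Fcrls, an Fc receptor-like protein, fell to 1103 ± 112 from 4686 ± 734 CPM. Of 16 border and perivascular macrophage genes 14 rose and 1 fell, 15 and 1 adjusted over the list alone (camera adjusted p = 1.08e-09, adjusted p = 0.0206 with an estimated correlation), but from low levels. Mrc1 reached 52.1 ± 23.9 CPM and Stab1, a scavenger receptor, fell to 60.4 ± 19.9 from 177 ± 60.9 CPM. The alternatively activated macrophage list had 9 of 10 genes higher, 9 adjusted over the list alone (camera adjusted p = 4.70e-06), with Retnla at 26.4 ± 11.6 CPM. Of 12 MHC class II genes 10 rose and none fell, 11 adjusted over the list alone (camera adjusted p = 1.33e-06), H2-Aa to 160.3 ± 44.1 CPM and Ctss to 23732 ± 2804 from 9101 ± 1517 CPM. In the optic nerve, replicate 4 had the highest level of 7 of the 11 border and perivascular macrophage genes that sciatic nerve expressed at 100 CPM or more and brain below 1 CPM.

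Interferon and disease-associated genes rose in optic nerve. The type I interferon list had 15 of 16 genes higher, 15 adjusted over the list alone (camera adjusted p = 3.52e-09, adjusted p = 0.0563 with an estimated correlation), with Ifi204 at 139 ± 19.8 against 6.57 ± 3.03 CPM. Of 16 disease-associated microglia genes 12 rose and none fell, 13 adjusted over the list alone (camera adjusted p = 2.14e-07). Lgals3, a galectin, rose to 94.1 ± 19.8 from 3.88 ± 1.82 CPM, Cst7, a cystatin, to 57.4 ± 11.9 from 13.98 ± 4.93 CPM and Itgax, an integrin, to 29.3 ± 9.58 from 5.87 ± 3.81 CPM. Complement genes rose in 8 of 12 cases with none lower, 8 adjusted over the list alone (camera adjusted p = 4.46e-04), and C4b reached 76.3 ± 38.3 from 1.60 ± 1.33 CPM.

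Inflammatory and early response genes were high in the optic nerve too. Chemokines rose in 16 of 17 cases, 17 adjusted over the list alone (camera adjusted p = 1.10e-13), inflammatory cytokine genes in 9 of 12, 9 adjusted over the list alone (camera adjusted p = 1.98e-10), and immediate early genes in 19 of 20, 19 adjusted over the list alone (camera adjusted p = 2.25e-20). With an estimated correlation the camera adjusted p of these lists was 0.0194, 0.0129 and 0.00908 in the same order. Tnf measured 1346 ± 243 against 1.50 ± 0.691 CPM and Il1a 5376 ± 1225 against 124 ± 18.5 CPM. Ptgs2, the inducible cyclooxygenase, and Sphk1, a sphingosine kinase, had 0 counts in brain and were at least 2972-fold and at least 3129-fold higher. Acod1, which makes itaconate, was at least 1638-fold higher, and Gadd45b, a stress-induced gene, reached 753 ± 193 CPM (log2 fold change 10.28, SE 0.42). The labels give no step that would tell nerve and brain preparations apart.

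Other groups moved less evenly between optic nerve and brain. Iron handling genes rose in 8 of 14 cases and fell in 2, 9 and 2 adjusted over the list alone (camera adjusted p = 0.00764, adjusted p = 0.0579 with an estimated correlation), with Slc40a1 lower at 77.5 ± 13.1 CPM. Of 26 transcription factors 10 rose and 9 fell, 13 and 9 adjusted over the list alone (camera adjusted p = 0.144), Nr4a1 rising to 323 ± 28.0 from 0.949 ± 0.817 CPM. Oligodendrocyte genes rose in 3 of 6 cases, 3 adjusted over the list alone (camera adjusted p = 0.0231, adjusted p = 0.0579 with an estimated correlation), with Mbp, the myelin basic protein, at 109 ± 13.4 against 34.5 ± 5.82 CPM. Lower genes included Tmem204 (log2 fold change -5.13, SE 0.42), Gpr165 (log2 fold change -5.07, SE 0.86), Fam212a (log2 fold change -3.66, SE 0.19) and Nid2, a basement membrane protein (log2 fold change -3.31, SE 0.28). Zinc finger genes Zfp748 and Zfp157 and the kinase gene Pdik1l also fell (-3.10, -3.35 and -3.20 in log2). In all, 2590 of 13246 genes were higher and 2303 lower in optic nerve than in brain, of which 1675 and 1650 by at least 2-fold. No overlap between libraries was found for 4213 genes (31.8%), against 1.59% by chance.

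**Figure D3:**
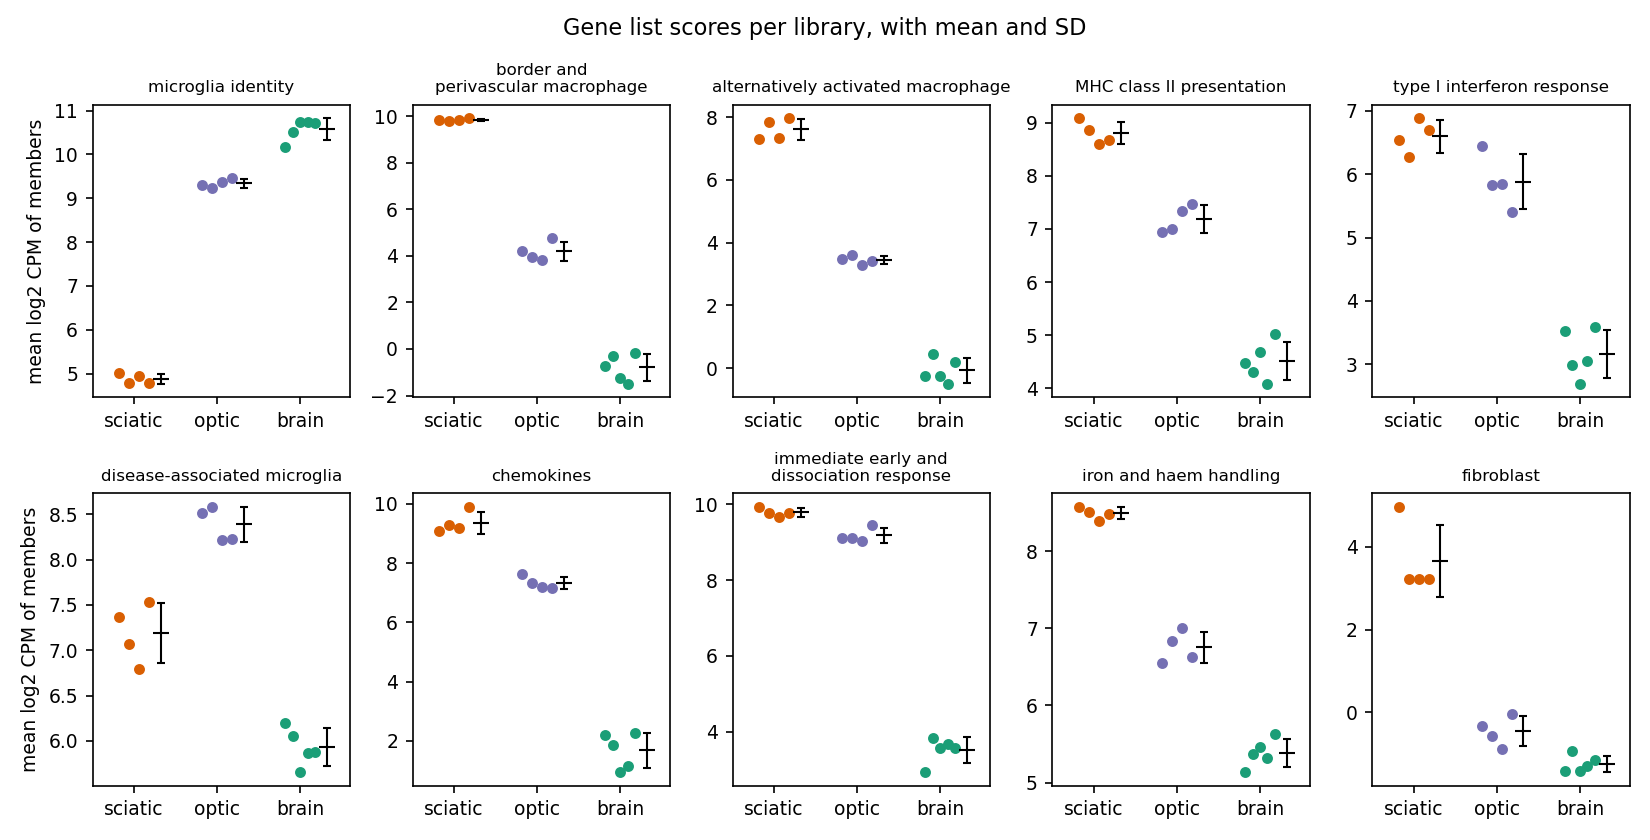
Mean log2 CPM of the tested members of 10 gene lists in each library (points), by tissue, with the group mean and SD. Microglia identity was 10.58 ± 0.25 in brain, 9.34 ± 0.09 in optic nerve and 4.88 ± 0.12 in sciatic nerve, and border and perivascular macrophage genes ran from -0.79 ± 0.58 through 4.19 ± 0.41 to 9.85 ± 0.05.

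Between the nerves, Cd209 genes were among the most raised in sciatic nerve, and Pdcd1 and Cd34 among the most lowered. Cd209f, a C-type lectin, measured 1147 ± 185 CPM in sciatic and 1.03 ± 0.704 CPM in optic nerve (log2 fold change 10.14, SE 0.51), and Cd209d 529.8 ± 43.4 against 0.255 ± 0.162 CPM (log2 fold change 10.96, SE 0.33). Pdcd1, an inhibitory checkpoint receptor, measured 0.140 ± 0.128 CPM in sciatic and 114 ± 19.95 CPM in optic nerve (log2 fold change -9.63, SE 0.62), and Cd34, a sialomucin of progenitor cells, 2.07 ± 0.963 against 648 ± 11.1 CPM (log2 fold change -8.29, SE 0.33). The adjusted p of these 4 genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 1.75e-10 to 2.86e-08. The Cd209 genes are close paralogs whose shared reads could be split between them, so the level of each is uncertain.

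Microglia identity genes fell in sciatic nerve relative to optic nerve in 16 of 18 cases, with 16 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.81e-19, adjusted p = 0.00645 with an estimated correlation). All 16 border and perivascular macrophage genes rose, also adjusted over the list alone (camera adjusted p = 1.26e-17, adjusted p = 0.00645 with an estimated correlation), Mrc1 with a log2 fold change of 5.25 (SE 0.42) and Cd163 of 5.49 (SE 0.37). Of 10 alternatively activated genes 7 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 3.24e-06). Socs2, a suppressor of cytokine signalling, was the gene that fell, at 1.03 ± 0.567 against 15.3 ± 7.72 CPM. Iron handling genes rose in 11 of 14 cases, 11 adjusted over the list alone (camera adjusted p = 9.48e-06), with Spic, a transcription factor of iron-recycling macrophages, at 45.6 ± 12.6 against 0.634 ± 0.824 CPM. Fibroblast genes moved the same way, 6 of 8 higher and 8 adjusted over the list alone (camera adjusted p = 1.81e-06), with Dcn at 0.0726 ± 0.112 CPM in optic nerve.

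MHC class II genes rose in 7 and fell in 4 of 12 cases between the nerves, 7 and 5 adjusted over the list alone, and the list was not called (camera adjusted p = 0.203). The disease-associated list was not called either, with 3 higher and 6 lower of 16, 6 and 7 adjusted over the list alone (camera adjusted p = 0.0848, and 0.0486 without optic nerve replicate 4). Cst7 and Itgax fell (-7.98 and -6.34 in log2) and Apoe rose (1.45). Complement genes gave 3 higher and 5 lower of 12, 5 and 5 adjusted over the list alone (camera adjusted p = 0.925), with a negative median and test direction and a positive mean. Transcription factors gave 11 higher and 5 lower of 26, 12 and 6 adjusted over the list alone (camera adjusted p = 0.305), and Tfec was 1659-fold, 95% counting interval 298 to 65540.5, higher. Inflammatory cytokine genes gave 5 higher and 2 lower of 12, 6 and 3 adjusted over the list alone (camera adjusted p = 0.0952), Il6 rising to 134 ± 20.2 from 13.3 ± 4.98 CPM and Il1a falling to 2085 ± 292 CPM.

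Chemokines rose in 9 and fell in 1 of 17 cases, 10 and 1 adjusted over the list alone (camera adjusted p = 9.48e-06, adjusted p = 0.172 with an estimated correlation), and Pf4, a platelet-type chemokine, reached 2891 ± 425 against 44.0 ± 16.3 CPM. Type I interferon genes rose in 6 of 16, 7 adjusted over the list alone (camera adjusted p = 0.0432, adjusted p = 0.431 with an estimated correlation), and immediate early genes rose in 7 and fell in 2 of 20, 9 and 2 adjusted over the list alone (camera adjusted p = 0.0432, adjusted p = 0.374 with an estimated correlation). The interferon call ended without sciatic nerve replicate 1, 3 or 4 or optic nerve replicate 2, 3 or 4, with adjusted p up to 0.112 without optic nerve replicate 4. The immediate early call ended without sciatic nerve replicate 1 or 4 or optic nerve replicate 1, 2 or 3, with adjusted p up to 0.0803 without sciatic nerve replicate 1. Ier3, an early response gene, rose to 2503 ± 401 from 507 ± 34.4 CPM and Ifitm3 to 1229 ± 149 from 207 ± 63.4 CPM.

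Further named genes set the nerves apart. Gprc5c, an orphan receptor, was 2127-fold, 95% counting interval 589 to 17561, higher in sciatic nerve, Enpep, the glutamyl aminopeptidase, 1755-fold, 95% counting interval 601 to 8511, higher, C1qtnf1 4738-fold, 95% counting interval 850.5 to 187157, higher and Slc7a13 1381-fold, 95% counting interval 382 to 11406, higher. Cd209b and Cd209g were higher with log2 fold changes of 11.92 and 10.98. Lower in sciatic nerve were Lrrc3 (-9.77 in log2), Capn3, a calpain (-9.30), Liph, a lipase (-9.20), Slc2a5 (-8.77), Spint1, a protease inhibitor (-8.76), and Tmem8c, 1069-fold, 95% counting interval 296 to 8829.7, lower. Capn3 shares exons with Ganc on the same strand, so its counts cannot be assigned with certainty. In all, 1447 of 13246 genes were higher and 1445 lower in sciatic than in optic nerve, of which 1097 and 1040 by at least 2-fold, and libraries did not overlap for 3961 genes (29.9%), against 2.86% by chance.

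**Figure D4:**
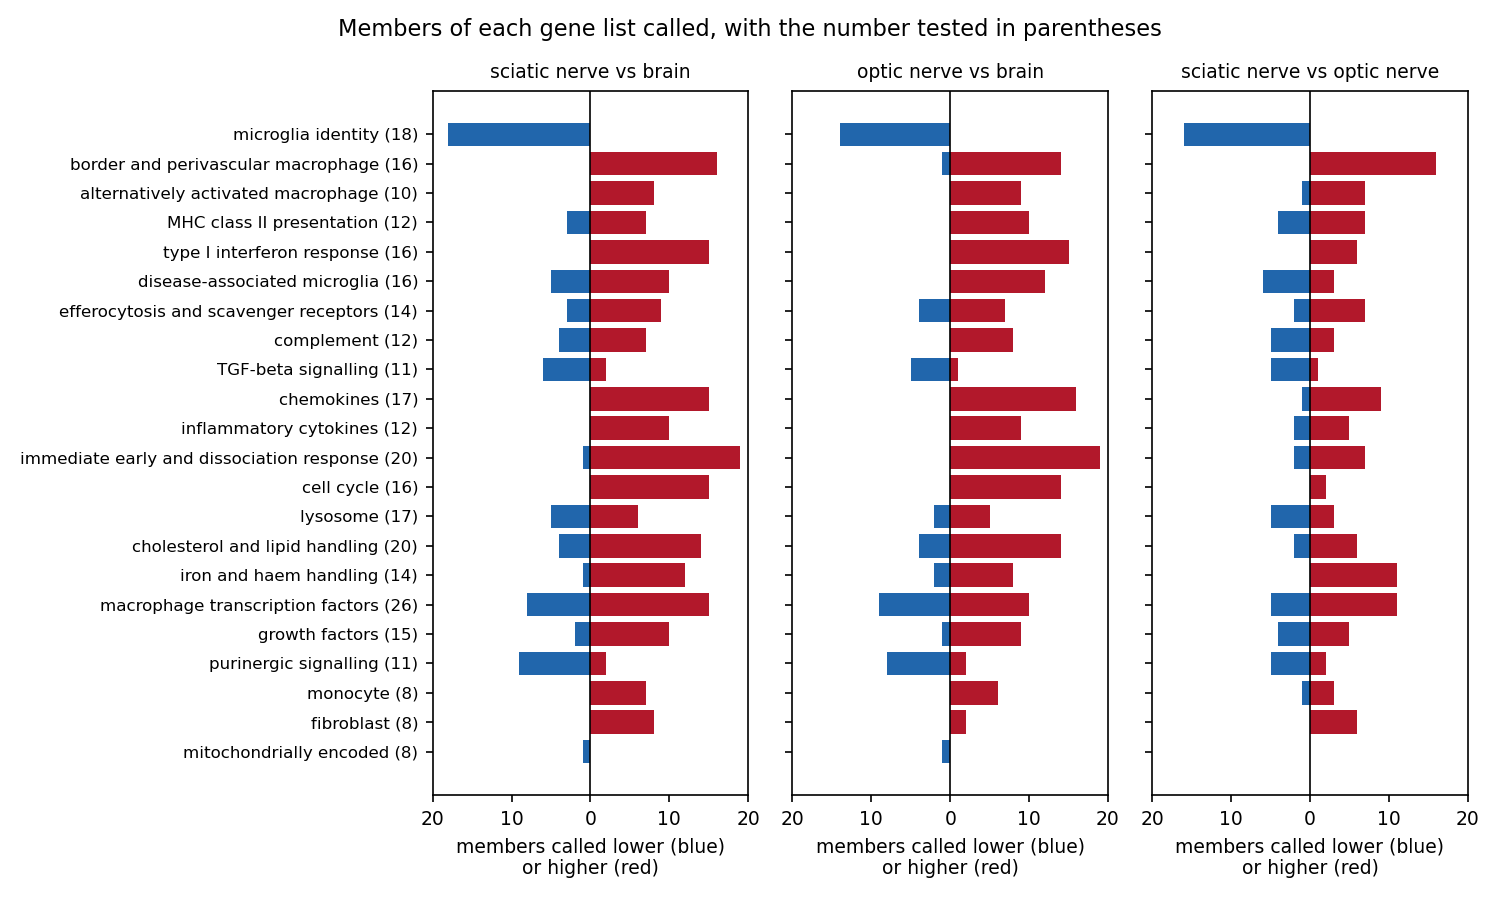
Number of members of each gene list called lower (blue) and higher (red) in the 3 comparisons, 1 panel each, by edgeR's quasi-likelihood test at adjusted p under 0.05. Lists with at least 8 tested members are shown, with the number tested in parentheses. Microglia identity is called lower for 18 of 18 members in sciatic nerve against brain, and border and perivascular macrophage genes are called higher for 16 of 16.

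Genes that set 1 tissue apart from both others were found most often for brain. Higher in brain than in both nerves were 1576 genes and lower 2055, led by Tmem204, Sall1, Fam212a, Trmt12 and Tmc7 on the higher side and Cxcl2, Cxcl1, Sphk1, Ptgs2 and Fosb on the lower. Sciatic nerve had 1107 genes higher than in both others, led by Cd209b, Cd209g, Cd209d, Enpep and Gprc5c, and 1116 lower, led by Lrrc3, Liph, Slc2a5, Spint1 and Capn3. Optic nerve had 335 higher and 310 lower. Pdcd1 stood out there at 5.05 ± 2.32 CPM in brain, as did Hcar2, the receptor for niacin and hydroxybutyrate (48.5 ± 10.1, 632 ± 99.6 and 6.08 ± 3.84 CPM in sciatic nerve, optic nerve and brain), and Adamts1, an extracellular protease (9.38 ± 4.55, 209 ± 41.8 and 4.63 ± 2.03 CPM). Olr1, a receptor for oxidised lipoprotein, and Mobp, a myelin protein, were also higher in optic nerve than in both others. Bank1 (18.9 ± 8.24 CPM), Rnf145, Clcn5, Maf and Zfyve21 were lower. Without brain replicates 1 and 2, a choice made after the data were seen, optic nerve had 587 genes higher and 480 lower.

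The pairs of comparisons behind these counts share libraries. Independent lists of the same sizes would share 349 and 351 genes for sciatic nerve higher and lower, 283 and 252 for optic nerve, and 560 and 624 for brain. In 10 simulations without any difference, 0 genes were shared. With no gene changed, few calls were possible there. This 0 therefore does not show how many shared calls the shared libraries add where many genes differ. With the shared libraries split into 2 parts, the shared calls were 742 and 738 for sciatic nerve higher and 712 and 734 lower, 167 and 170 for optic nerve higher and 119 and 122 lower, and 962 and 982 for brain higher and 1545 and 1572 lower. Each part holds fewer libraries of the shared tissue, and the number of genes it called is not given here. These counts therefore cannot be set against the numbers for independent lists, which come from the full calls.

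Along the axis from brain to sciatic nerve, over all tested genes, the optic nerve lay midway between the other tissues. It also differed from both off this axis. On principal component 2 its libraries stood at -102.4 to -72.3, against 40.8 to 50.3 in sciatic nerve and 23.5 to 49.4 in brain. On the axis from brain (0) to sciatic nerve (1) the 4 optic nerve libraries stood at 0.503 ± 0.0191 (SD, n = 4), with a range from 0.480 to 0.526. Their mean distance per gene in log2 units was 1.86 ± 0.0322 to sciatic nerve and 1.91 ± 0.0752 to brain, a difference of -0.0484 ± 0.0488. An exact two-sided permutation test over all assignments of the brain and sciatic nerve libraries gave p = 0.595, where the smallest possible p is 0.00794, so a nearer tissue was not shown. With the 1000 genes of highest variance the difference turned to 0.233 (exact permutation p = 0.0159), nearer to brain. This test called a nearer tissue in 20.5% of 200 simulations that had none, so a p under 0.05 alone does not establish one. The differences in those simulations ran from -0.0273 to 0.0223, a far narrower range than 0.233. They placed the optic nerve exactly on the axis, unlike these libraries, so they cannot decide about this result either way. Over all tested genes and without brain replicate 1, the difference in distance was 0.00951 in log2 units. The labels give no preparation per library. A preparation shared by the nerves and not by brain would shift the position and the distances, and it cannot be told apart from the tissues. The same holds for every comparison with brain.

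Csf1r, the receptor for colony-stimulating factor, measured 4756 ± 790.1, 7029.6 ± 876 and 10965 ± 4459.7 CPM in sciatic nerve, optic nerve and brain, and Ptprc, the pan-leukocyte phosphatase, 509 ± 85.7, 527 ± 28.3 and 276 ± 58.2 CPM. Adgre1, which encodes the macrophage marker F4/80, rose in sciatic nerve and fell in optic nerve relative to brain (1.14 and -0.89 in log2), and Fcgr1, a high-affinity Fc receptor, fell in sciatic nerve (-0.89). Ccr2, the monocyte chemokine receptor, measured 458 ± 70.6 CPM in sciatic nerve, 9.49 ± 4.08 in optic nerve and 4.01 ± 3.68 in brain, and was called only for the comparisons with sciatic nerve.

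Markers of other cells were measured beside these groups. Only part of these lists passed the filter, as with 3 of 11 neutrophil, 3 of 14 lymphoid and 3 of 12 Schwann cell genes. The counts are of tested genes. Monocyte genes rose in 7 of 8 cases in sciatic nerve (camera adjusted p = 9.65e-05) and 6 in optic nerve (8 adjusted over the list alone, camera adjusted p = 1.91e-05) relative to brain, and 3 rose and 1 fell between the nerves (camera adjusted p = 0.0867). Of 3 neutrophil genes 2 rose and 1 fell in sciatic nerve (camera adjusted p = 0.0863), 2 rose in optic nerve (camera adjusted p = 0.0145, adjusted p = 0.0563 with an estimated correlation), and 1 rose and 1 fell between the nerves (camera adjusted p = 0.0867). Mmp9, a gelatinase, was the sciatic nerve gene among them at 544 ± 44.6 CPM. The 2 neutrophil genes that rose in optic nerve were at low levels there, Mmp9 at 1.99 ± 0.725 CPM and Retnlg at 0.464 ± 0.105 CPM. Dendritic cell genes gave 5 higher and 2 lower of 7 in sciatic nerve, 4 higher in optic nerve, and 1 and 2 between the nerves (camera adjusted p = 0.151, 0.105 and 0.7496). Cd209a reached 358 ± 39.8 CPM in sciatic nerve. Lymphoid genes gave 1 higher and 1 lower of 3 in both nerves against brain and 1 higher between the nerves (camera adjusted p = 0.486, 0.972 and 0.0865), and in optic nerve against brain the median and mean were positive and the test direction was down. Adjusted over the list alone, the counts between the nerves were 2 and 1 for neutrophil and 2 and 3 for dendritic cell genes, and the other counts not given beside the lists were the same.

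Cells of nerve and brain tissue were traced by further lists. Schwann cell genes rose in 2 of 3 cases in sciatic nerve against brain (camera adjusted p = 0.101, with a call without sciatic nerve replicate 2 or any optic nerve library, down to 0.0166), in 0 in optic nerve (camera adjusted p = 0.896) and in 2 between the nerves (camera adjusted p = 0.0432, adjusted p = 0.172 with an estimated correlation, a call that ended without sciatic nerve replicate 1, 3 or 4, with adjusted p up to 0.0622 without replicate 3). Oligodendrocyte genes gave 2 higher and 1 lower of 6 in sciatic nerve against brain (2 and 2 adjusted over the list alone, camera adjusted p = 0.748) and 3 lower between the nerves (camera adjusted p = 0.0867). Mobp, in optic nerve, measured 33.1 ± 16.0 CPM. Fibroblast genes in optic nerve against brain rose in 2 of 8 cases, 4 adjusted over the list alone (camera adjusted p = 0.329). Astrocyte genes gave 1 and 1, 2 and 2, and 1 and 2 higher and lower of 5 in the 3 comparisons in turn (camera adjusted p = 0.972, 0.486 and 0.383). Slc1a3, a glutamate transporter, was highest in brain at 211 ± 24.9 CPM. Endothelial genes gave 1 and 1, 0 and 1, and 1 and 2 of 4 (camera adjusted p = 0.437, 0.916 and 0.174), with Pecam1 at 29.1 ± 11.7 CPM in brain. Adipocyte and muscle genes rose in 2, 0 and 1 of 3 cases (camera adjusted p = 0.0863, 0.706 and 0.0865), and without sciatic nerve replicate 2 the adjusted p was 0.0463 in sciatic nerve against brain and 0.0473 between the nerves. Adjusted over the list alone, astrocyte genes gave 2 and 1, 3 and 2, and 2 and 2, endothelial genes 1 and 1 in optic nerve against brain, and the other counts whose adjusted numbers are not given beside them were the same. Median, mean and test differed in sign for astrocyte genes in sciatic nerve against both others and for Schwann cell and endothelial genes in optic nerve against brain.

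Mitochondrially encoded genes fell in 1 of 8 cases in each nerve against brain and in 0 between the nerves (camera adjusted p = 0.805, 0.202 and 0.339). The lists for neurons, mast cells and sex-linked genes had fewer than 3 tested members and no list test. Of 2 neuron genes, Snap25 fell in sciatic nerve against brain (log2 fold change -5.35, SE 1.85), a call that ended without sciatic nerve replicate 1, 2 or 3 (-4.94, -4.95 and -4.96), without brain replicate 1 (-3.92), without brain replicates 1 and 2 (-2.57) or with a replicate block (-5.55). Syn1 was higher in sciatic than in optic nerve, 69.3-fold, 95% counting interval 12.4 to 2737, a call that ended when any of 8 single libraries was left out, all but sciatic nerve replicate 2 among the nerve libraries and, in brain, replicate 3. It also ended without a filter, with DESeq2, with limma-voom and with a replicate block (5.58, 5.87, 3.86 and 5.88 in log2). In optic nerve against brain no neuron gene was called, and 1 was lower adjusted over the list alone. Hdc, the mast cell gene tested, was higher in sciatic nerve than in brain, 181-fold, 95% counting interval 32.4 to 7132, and in optic nerve, 49.9-fold, 95% counting interval 8.96 to 1972, and was not called between the nerves. Xist, of the sex-linked list, fell in both nerves against brain (-1.35 and -1.72 in log2), and the sciatic nerve call ended without sciatic nerve replicate 1, 3 or 4 (-1.25, -1.35 and -1.18) or brain replicate 1 (-0.90). Both calls ended without brain replicates 1 and 2 (-0.49 and -0.85).

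Positions in the mouse assembly GRCm38 place Sall1 on chromosome 8, 89027235 to 89044162, P2ry12 on chromosome 3, 59216272 to 59262871, Tmem119 on chromosome 5, 113793729 to 113800516, Retnla on chromosome 16, 48842551 to 48844461, Cd163 on chromosome 6, 124304656 to 124330527, H2-Aa on chromosome 17, 34282744 to 34287823, Cxcl2 on chromosome 5, 90903871 to 90905938, Apoe on chromosome 7, 19696109 to 19699188, Pdcd1 on chromosome 1, 94038305 to 94052553 and Hcar2 on chromosome 5, 123863570 to 123865499, each a protein-coding gene. Of the genes with printed values, P2ry12, Cx3cr1, Csf1r, Stab1, Cd34, C1qtnf1, H2-Oa, Il1a, Maf, Nid2, Sphk1, Syn1 and Zfp748 overlap exons of another gene on the other strand (Med12l for P2ry12, Hmgxb3 for Csf1r and Nt5dc2 for Stab1). Ctsd, Itgam and Mobp share exons with a predicted gene on the same strand, as Capn3 does with Ganc, and Xist overlaps genes on both strands, among them Tsix. The strand setting of the counting is not given in the sources used here, so reads of these genes and their partners cannot be told apart.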

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

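The tests of library scaling, preparation, ribosomal RNA, a uniform share and a border-type minority were chosen after the results were seen, and the other tests before. A value was singled out when the gap between the highest or lowest library of a group and its nearest neighbour was large against the range of the group (Dixon's test). Chance singles out about 1 in 20 groups, and 13 of 247 groups tested were singled out here, 3 of them by brain replicate 1.

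In brain replicate 1 the share of mitochondrially encoded counts was 3.79%, with the nearest brain library at 0.868%, Tmem119 measured 3123 CPM with the nearest at 4915 CPM, and Tmem204 measured 55.2 CPM with the nearest at 103.0 CPM. In sciatic nerve, the mean log2 CPM of the fibroblast list was 4.96 in replicate 1 with the nearest at 3.22, and that of the endothelial list was 1.10 in replicate 4 with the nearest at -0.59. Cd209d measured 594.7 CPM and Il10 318.8 CPM in sciatic nerve replicate 4, with the nearest at 514.4 and 197.4 CPM. Il1a measured 1648 CPM in sciatic nerve replicate 1 with the nearest at 2195 CPM, and Socs2 1.87 CPM in sciatic nerve replicate 2 with the nearest at 0.850 CPM. In optic nerve replicate 4, Adamts1 measured 271.2 CPM with the nearest at 190.7 CPM and Stab1 90.1 CPM with the nearest at 53.3 CPM. Apoe measured 480.2 CPM in brain replicate 2 with the nearest at 304.7 CPM, and H2-Aa 6.22 CPM in brain replicate 5 with the nearest at 1.59 CPM.

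Immediate early and inflammatory transcripts were higher in both nerves than in brain. Library scaling is argued against, since the smallest median log2 fold change of the 32 members over 3 scalings and both nerves was 5.34. A preparation that differed between nerve and brain libraries cannot be told apart from the tissues, since the labels give no preparation per library and 87.5% of the members (28 of 32) were higher in both nerves, against 15.5% of all genes tested. A response to taking the cells from the tissue may then account for the pattern. A difference between the tissues themselves stays open too and was not tested.

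Brain replicate 1 stood apart from the other brain libraries, with a mean correlation lower by 0.0317 than the lowest of the others. Lower depth is argued against, since the gap was at least 0.0313 after the other libraries were thinned to the same depth 10 times, and so is a trend on GC content and transcript length, since 0.0291 remained after its removal from 12842 genes. The 7 loci tested as ribosomal RNA, chosen since they were seen to differ, were higher in this library by 3.11 to 4.54 in log2 than in the mean of the other brain libraries. They include 2 that are not ribosomal RNA loci, the small nuclear RNA gene Rn7sk (4.54) and the protein-coding gene Lars2 (4.00). Ribosomal RNA carried into the library is argued against as the whole cause of the gap, since 0.0264 remained without these 7 loci, mitochondrially encoded genes and unnamed or small RNA loci (1744 genes). Nuclear RNA carried into the library is a candidate explanation for part of it, since the median of a list of nuclear-retained RNAs was higher by 1.59 in log2 in this library than in the mean of the other brain libraries, with 9 of 10 tested members above 0 and Malat1 at 3.63. It does not account for the rise of mitochondrially encoded ribosomal RNA (mt-Rnr1 3.37, mt-Rnr2 3.11), so another or a wider source stays open. Some neural transcripts were higher in this library too, with Snap25 at 20.5 CPM (0.606 to 5.98 in the other brain libraries), Aldoc at 23.6 CPM (1.17 to 3.29), Mobp at 8.61 CPM (0.819 to 2.12) and a mean log2 CPM of the oligodendrocyte list of 2.13 (0.25 to 0.86), while Mbp at 33.7 CPM (28.6 to 44.1) and the astrocyte list at 0.48 (0.04 to 1.00) were not. RNA of neural cells carried into the library was not tested and stays open. No biological explanation was tested, since the labels do not separate this library from the others.

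Of 87 genes abundant in sciatic nerve macrophages and nearly absent from brain, 50 measured under 5% of the sciatic nerve level in optic nerve and 6 over 50%, up to 115% for Dusp2 and 112% for Maff, with a median of 3.98%. A uniform share of sciatic-type RNA is argued against, since the share of the 90th percentile was 86.9 times that of the 10th. A minority of border-type macrophages in the optic nerve libraries may account for part of the pattern, since 63.6% of the border and perivascular macrophage members (7 of 11) were highest in replicate 4, where chance gives as many in any 1 library in 3.02% of cases. The levels of these 11 members in optic nerve were however uneven, from 0.0471% to 9.28% of the sciatic nerve level with a median of 3.11%. These members move together and are not independent, and lower expression in all optic nerve macrophages was not tested and stays open.

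The numbers of called genes were compared with other splits of the same libraries. Of 100 splits, 1, the real one, called as many genes in sciatic nerve against brain (6410, with the highest other at 4148). In optic nerve against brain it was also 1 of 100 (4893, with the highest other at 3288), and in sciatic against optic nerve 1 of 35 (2892, with the highest other at 0). The other splits mix the tissues, which adds to the spread, so the real split was likely to call the most genes. These splits therefore do not exclude chance, and they cannot speak for animals if the replicates are technical. In both comparisons with brain the highest other split exchanged 4 libraries, so that 4 brain libraries stood against the nerve and the other brain library.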

How the results depend on the processing

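The setting without brain replicates 1 and 2 was chosen after the data were seen, and the others before. Of the fold changes of named genes, 7669 kept the side of the threshold over the alternatives, and kept direction where called. A change of direction between 2 fits without a call counts among these. Further, 137 lost the call, 55 gained it and 0 reversed with a call in either fit. Of the results of list tests, 1519 were unchanged in the same sense, 56 lost the call and 39 gained it. Of counts of genes, 387 stayed within 1.5 times the reported value and 3 moved further. These were 1559 genes higher by at least 2-fold in sciatic nerve than in brain with a filter at 10 CPM, which tested fewer genes, and 587 genes higher and 480 lower in optic nerve than in both others without brain replicates 1 and 2, for which the cause was not tested. Leaving out 1 library in turn gave 239 to 442 genes for optic nerve higher and 212 to 416 for optic nerve lower, with the lowest without optic nerve replicate 3 and the highest without brain replicate 1. With the 1000 genes of highest variance the optic nerve was nearer to brain by 0.233 (exact permutation p = 0.0159) and its position was 0.473, and the cause was not tested. That test called 20.5% of simulations without a nearer tissue, where the difference ran from -0.0273 to 0.0223. Over the other alternatives the nearness ran from -0.0794 to 0.0520. The position without brain replicates 1 and 2 could not be computed, since both form a part of the split. Camera with an estimated correlation called 9, 11 and 5 of 30 lists in sciatic nerve against brain, optic nerve against brain and sciatic against optic nerve, in place of 16, 18 and 13, and fry, which does not compare a list with other genes, called 26, 24 and 25. Its adjusted p for the lists that camera called both ways ran from 0.0121 to 0.0453 with an estimated correlation in sciatic nerve against brain, and from 0.00908 to 0.0474 in optic nerve against brain. Far smaller camera p-values of lists rest on the preset correlation. Between the nerves, leaving out 1 library gave 7 (without sciatic nerve replicate 4) to 13 lists, and 8 without sciatic nerve replicate 1. The cause was not tested. A replicate block, with the replicate number as a factor, gave 5606, 3926 and 2478 called genes in place of 6410, 4893 and 2892, and changed no list call. The 12 correlations of same-numbered libraries ran from -0.0776 to 0.0773, 0 of them over 0.1, and 4 of 12 libraries correlated best with their own number. No strong pairing by number was seen, and a weak one is not excluded. Depth limits the lowest level that 0 counts allow (up to 0.0512 CPM in sciatic nerve). In simulations of sciatic against optic nerve 19.4% of genes changed by 1 in log2 were recovered, and the part of depth in this was not tested apart from the number and spread of the libraries.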

Other observations

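No test in this part was chosen after its result was seen. Scavenging, lipid and growth factor genes also differed between the tissues. Of 14 efferocytosis and scavenger receptor genes 9 rose and 3 fell in sciatic nerve against brain, the same adjusted over the list alone (camera adjusted p = 0.00288, adjusted p = 0.135 with an estimated correlation). Timd4, a phosphatidylserine receptor, measured 237 ± 33.3 CPM with 0 counts in brain (at least 8953-fold higher), while Mertk, a kinase receptor for dying cells, fell to 55.7 ± 11.3 from 675 ± 129 CPM (log2 fold change -3.60, SE 0.19). In optic nerve against brain 7 rose and 4 fell (camera adjusted p = 0.0934), and between the nerves 7 rose and 2 fell, 8 and 2 adjusted over the list alone (camera adjusted p = 0.00249, adjusted p = 0.189 with an estimated correlation). Of 20 cholesterol and lipid genes 14 rose and 4 fell in sciatic nerve (camera adjusted p = 0.00134, adjusted p = 0.0571 with an estimated correlation), 14 and 4 in optic nerve, 15 and 4 adjusted over the list alone (camera adjusted p = 9.65e-04, adjusted p = 0.0474 with an estimated correlation), and 6 and 2 between the nerves, 7 and 2 adjusted over the list alone (camera adjusted p = 0.0865). The cholesterol exporter genes Abca1 and Abcg1 fell in both nerves against brain (-1.21 and -2.35, -5.28 and -2.37 in log2). Growth factor genes gave 10 higher and 2 lower of 15 in sciatic nerve, 9 and 1 in optic nerve (9 and 2 adjusted over the list alone), and 5 and 4 between the nerves (camera adjusted p = 0.00960, 0.00171 and 0.887). Igf1, an insulin-like growth factor, measured 216 ± 15.5 CPM in sciatic nerve and 11.2 ± 4.03 CPM in optic nerve, and Csf1, which sustains macrophages, 142 ± 17.2 CPM in optic nerve against 14.8 ± 5.23 CPM in brain.

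Cell cycle genes rose in 15 of 16 cases in sciatic nerve (camera adjusted p = 5.17e-06, adjusted p = 0.0742 with an estimated correlation) and in 14 in optic nerve (camera adjusted p = 1.04e-05, adjusted p = 0.0620 with an estimated correlation), relative to brain, from low levels. Ccnb2, a mitotic cyclin, measured 10.6 ± 3.04, 7.06 ± 5.15 and 0.219 ± 0.184 CPM in sciatic nerve, optic nerve and brain. Between the nerves 2 rose, 1 adjusted over the list alone (camera adjusted p = 0.0432, adjusted p = 0.374 with an estimated correlation), a call that ended without sciatic nerve replicate 1, 2 or 4, optic nerve replicate 1 or 3 or brain replicate 1, with adjusted p up to 0.102 without optic nerve replicate 1. TGF-beta signalling genes gave 2 higher and 6 lower of 11 in sciatic nerve, 1 and 5 in optic nerve (camera adjusted p = 0.0759 and 0.144), and 1 and 5 between the nerves (camera adjusted p = 0.0434, adjusted p = 0.374 with an estimated correlation, and up to 0.0889 without sciatic nerve replicate 2, where leaving out any 1 nerve library or brain replicate 1 ended the call). The receptor gene Tgfbr1 measured 102 ± 36.1, 621 ± 35.6 and 2156 ± 743 CPM. Purinergic genes fell in 9 of 11 cases in sciatic nerve and rose in 2 (camera adjusted p = 0.00331, adjusted p = 0.122 with an estimated correlation), fell in 8 and rose in 2 in optic nerve (camera adjusted p = 0.0206, adjusted p = 0.196 with an estimated correlation), and fell in 5 and rose in 2 between the nerves (camera adjusted p = 0.0432, adjusted p = 0.273 with an estimated correlation, and up to 0.0560 without optic nerve replicate 1, where leaving out that library or sciatic nerve replicate 2, 3 or 4 ended the call). The receptor gene P2rx4 rose in both nerves against brain (1.64 and 0.62 in log2). The purinergic list also holds Adrb1, an adrenergic and not a purinergic receptor gene, at 2.21, 3.89 and 16.1 CPM in sciatic nerve, optic nerve and brain. Lysosome genes gave 6 higher and 5 lower of 17 in sciatic nerve, 5 and 2 in optic nerve, and 3 and 5 between the nerves (4 and 5 adjusted over the list alone), without a list call (camera adjusted p = 0.675, 0.202 and 0.662). Between the nerves the median of the list was -0.01 and its test direction was down, with a positive mean, and for growth factor genes the median was negative with a positive mean and test direction. Ctsd, a cathepsin, measured 890.1 ± 141, 10847 ± 542 and 10939 ± 1645 CPM. For these lists, and for the scavenging, lipid and growth factor lists, counts that stand without a number adjusted over the list alone were the same when so adjusted.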
